A study of Perca fluviatilis with 22 samples.

How the data were processed

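The series holds 22 RNA-seq libraries of perch tissue, 11 of liver and 11 of spleen, each with a title giving infection status, tissue and a number, and with a label for sex. Per the labels' protocols, tissue was crushed, total RNA was extracted with a column kit, and libraries were prepared by a sequencing provider. The submitters' processing notes name FastQC 0.11.9, fastp 0.20, HISAT2 2.1.1, SAMtools 1.10, R 4.2.2 and DESeq2 1.36.0, without saying what each did. The counting tool, strandedness, genome build and annotation are not given in the sources used here. Without strand or counting rules, reads of overlapping or near-identical genes cannot be told apart, and ATP8 and ATP6 overlap in vertebrate mitochondrial genomes.

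The deposited values are raw counts per gene, in 1 table per tissue. They are whole numbers with a different total in each library, and no further normalization was visible. Every row of both tables has at least 10 counts in at least 2 libraries, so low genes had been removed before deposit. The files held 0 columns beyond those of the 22 libraries. Columns were assigned to samples by the number in their names, which matched 1 title each. No pair of libraries in a group agreed within counting noise (chi-square per degree of freedom of at least 28.1), so each counted as 1 replicate. The labels do not state that each library is a separate fish, and p-values measure the spread between these libraries.

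Status was taken from the titles and the matching status labels. The bracketed letters in the column names, which give 6 infected and 5 uninfected libraries in each tissue if read as such, were used only as an alternative. Of the 18355 identifiers in the 2 tables, 0 matched the reference gene table in use. All 557 entries of the 21 gene lists fixed beforehand (immune, acute phase, blood and tissue cell markers, metabolism, stress, cell cycle, egg proteins and clock genes) therefore stayed unmatched, and no list was tested. Markers of other cell types could not be looked up either.

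Counts were analysed with edgeR 4.0.16 in R 4.3.3, with TMM scaling, the filterByExpr filter, robust quasi-likelihood fits and Benjamini-Hochberg adjustment at 0.05. Infection was tested in each tissue with sex as a term, sex with infection as a term, and the interaction of infection and tissue in a joint fit over genes in both tables. These models were set before the data were examined. SEs of log2 fold changes were derived from the F statistic. Named genes followed a rule set beforehand. Where fewer than 10 genes passed, those with the smallest p were named up to 10, and genes without a symbol were passed over. The mitochondrial features were the only rows with symbols. Identifiers named outside that rule are marked as such.

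Alternatives set beforehand were DESeq2 1.42.0, RLE size factors, no filter, at least 1 CPM in 5 libraries, number run as a term, fits without the covariate, limma-voom with quality weights (limma 3.58.1) and each library left out in turn. Status by letters, fits within number runs, the mitochondrial shares, the set tests, the test among number runs and the matching of libraries between tissues were added after the data were seen. DESeq2 was given the unfiltered counts, with its own size factors and its own filter for low counts. Its numbers of genes therefore differ from those of edgeR by more than the test. Shares of counts were compared with two-sided exact permutation tests, 462 assignments for 5 against 6 libraries. Liver and spleen were compared with 100000 permutations. Figures were drawn with matplotlib 3.10.9.

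The edgeR test was checked on simulated counts with the real means, dispersions and library sizes, in which 200 genes were changed. For infected against uninfected liver it recovered 11% of genes changed 2-fold and 64% of those changed 4-fold, among 14821 genes. For spleen it recovered 27% and 72% among 16460 genes. The interaction recovered 15% and 62% among 14260 genes. For sex the shares were 18% and 71% in liver among 14856 genes, and 25% and 70% in spleen among 16460 genes. With number run as a term, infection in spleen recovered 56% and 88% among 16528 genes. Library totals of 12132833 to 18610137 counts and the real dispersions entered these simulations.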

Results

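RNA was sequenced from liver and spleen of Eurasian perch (Perca fluviatilis) caught in several lakes. The fish did or did not carry plerocercoids, the larval stage of the tapeworm Triaenophorus nodulosus, in the liver. The liver is the organ the larvae occupy, and the spleen is a main immune organ of bony fish. By the sample titles there were 5 liver libraries from infected and 6 from uninfected perch, and likewise 5 and 6 spleen libraries. Females gave 3 of the 5 infected and 3 of the 6 uninfected liver libraries, and 3 of the 5 infected and 2 of the 6 uninfected spleen libraries. Total counts per library ran from 14535108 to 18610137 in liver and from 12132833 to 15724692 in spleen. Counts were deposited for 15377 genes in liver and 17246 in spleen, of which 14268 were in both. All but 16 rows of each table carried bare identifiers that the files do not pair with names. The 16 named features were the 13 mitochondrial messenger RNAs, the large and small mitochondrial ribosomal RNAs (l-rRNA and s-rRNA) and the proline transfer RNA, trnP(ugg).

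The infection status of many liver libraries was not certain. Each column name carried a bracketed letter, U or I, that the files do not define. Read as uninfected and infected, the letters contradicted the titles in 7 of the 11 liver libraries and in 1 of the 11 spleen libraries. The groups below follow the titles, and values under the letters are given beside the main infection results. Fits by limma-voom, within number runs and without 1 library were made by titles alone. The titles also carried numbers in 3 separate runs: 38 to 59, 293 to 314 and 469 to 489. The labels do not say what these runs are or which lake a fish came from. The order of the liver column headings is itself in doubt, as described in the closing section, so the liver results hold only if those headings are right.

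The first comparison asked which liver transcripts differed between infected and uninfected perch. Mitochondrial features took 1.18% ± 0.28 (SD, n = 5) of the counts in infected and 1.39% ± 0.24 (SD, n = 6) in uninfected livers. The difference of -0.214 percentage points was within the spread of the libraries (two-sided exact permutation test, p = 0.219, and 0.323 after Benjamini-Hochberg adjustment over both tissues). Under the letters it was -0.194, and within the runs numbered 294 to 314 and 469 to 489 it was -0.365 and -0.315. Livers 59, 314, 469 and 474 had the lowest shares (1.12, 0.98, 0.97 and 0.98%), against 1.28 to 1.77% in the others. They also lie together on the first principal component of liver, at -50.2 to -45.2, against 13.1 to 39.0 in the others. All but 59 are titled infected, so the difference cannot be told apart from this cluster. The values within runs rest on the same libraries and are no separate evidence. COX1 and COX3, subunits of cytochrome c oxidase, had log2 fold changes of -0.33 ± 0.27 (SE) and -0.36 ± 0.28 (SE). Mean COX3 levels were 1750 ± 788 CPM (SD, n = 5) in infected and 2229 ± 396 CPM (SD, n = 6) in uninfected livers. COX2, the remaining subunit of that enzyme encoded in mitochondria, had a log2 fold change of -0.21 ± 0.23 (SE), and CYTB, the cytochrome b of complex III, one of -0.22 ± 0.25 (SE). The complex I subunits ND1, ND2, ND5 and ND6 had log2 fold changes of -0.18, -0.13, -0.23 and -0.31, with SEs of 0.29, 0.29, 0.43 and 0.30. The estimate was 0.34 ± 0.38 (SE) for s-rRNA and -0.59 ± 0.69 (SE) for trnP(ugg).

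None of these 10 features, which had the smallest p among the named features, passed the test. Under the letters COX1, COX3, COX2 and CYTB were at -0.38, -0.41, -0.30 and -0.30, and ND1, ND2, ND5 and ND6 at -0.53, -0.55, -0.69 and -0.35. There s-rRNA was at 0.52 and trnP(ugg) at -1.34, and none passed. In the 4 libraries whose title and letter agree, 2 of each status, COX3 was at -1.14 and COX1 at -0.96, without passing. The infected 314 and 474 of these lie at -45.2 and -50.2 on the first principal component of liver. The uninfected 299 and 489 lie at 30.1 and 19.7, so status cannot be told apart from that cluster here. With number run as a term and all libraries, COX3 and COX1 were at -0.58 and -0.55. Leaving out 1 library moved all 10 estimates over 1.5-fold, for ND5 to between -0.73 and -0.03 and for COX3 to between -0.64 and -0.23. Over all 16 named features, 12 had estimates below 0 in infected liver and 4 above, with a median log2 fold change of -0.15. Under the bracketed letters 13 were below 0 and the median was -0.39. Taken as a set, the 13 mitochondrial messenger RNAs lay below other genes (camera with a preset correlation, p = 0.018). The correlation estimated from the libraries was 0.56, far above the preset one, so that p is too small. With the estimated correlation the set did not pass (camera, p = 0.394). Fry, a rotation test that allows for correlation among genes, asks whether the set differs from no change and gave p = 0.410. Under the letters the preset correlation gave p = 8.91e-06, the estimated correlation 0.120 and fry 0.085.

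Across the 15040 liver genes tested, 0 passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, and 732 had an unadjusted p below 0.05. Under the bracketed letters edgeR also gave 0. DESeq2 gave 2 genes under the titles and 21 under the letters, and limma-voom gave 0 under the titles. With number run as a term edgeR gave 0 under titles and letters alike, and DESeq2 gave 96 and 12. Within the run from 469, with 2 libraries of each status, edgeR called 437 genes, 247 higher and 190 lower in infected, and within the run from 294 it called 0. The infected livers of the former run, 469 and 474, lie at -49.5 and -50.2 on the first principal component, near livers 59 and 314 at -49.9 and -45.2. The uninfected 479 and 489 lie at 13.1 and 19.7, and the headings of these livers are among those in doubt. Of the 10 features above only trnP(ugg) passed within that run, at -2.51. Both genes that DESeq2 called under the titles without number run are named here after their values were seen. The count filter removed them before the edgeR test. Without a filter edgeR did not pass them (adjusted p = 0.908 each). PFLUV_G00167670 was at 0 counts in the 5 infected livers, at 189 to 318 CPM in 4 uninfected livers and at 0 or 1 count in the other 2 (DESeq2 adjusted p = 0.003). PFLUV_G00217700 averaged 1.89 ± 1.81 CPM (SD, n = 5) in infected and 0.056 ± 0.088 CPM (SD, n = 6) in uninfected livers (DESeq2 adjusted p = 0.011). Under the letters neither passed. The DESeq2 log2 fold change went from -13.85 to -10.27 for the first (adjusted p = 0.163) and from 4.95 to -1.06 for the second, a change of sign (adjusted p = 0.971).

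**Figure D1:**
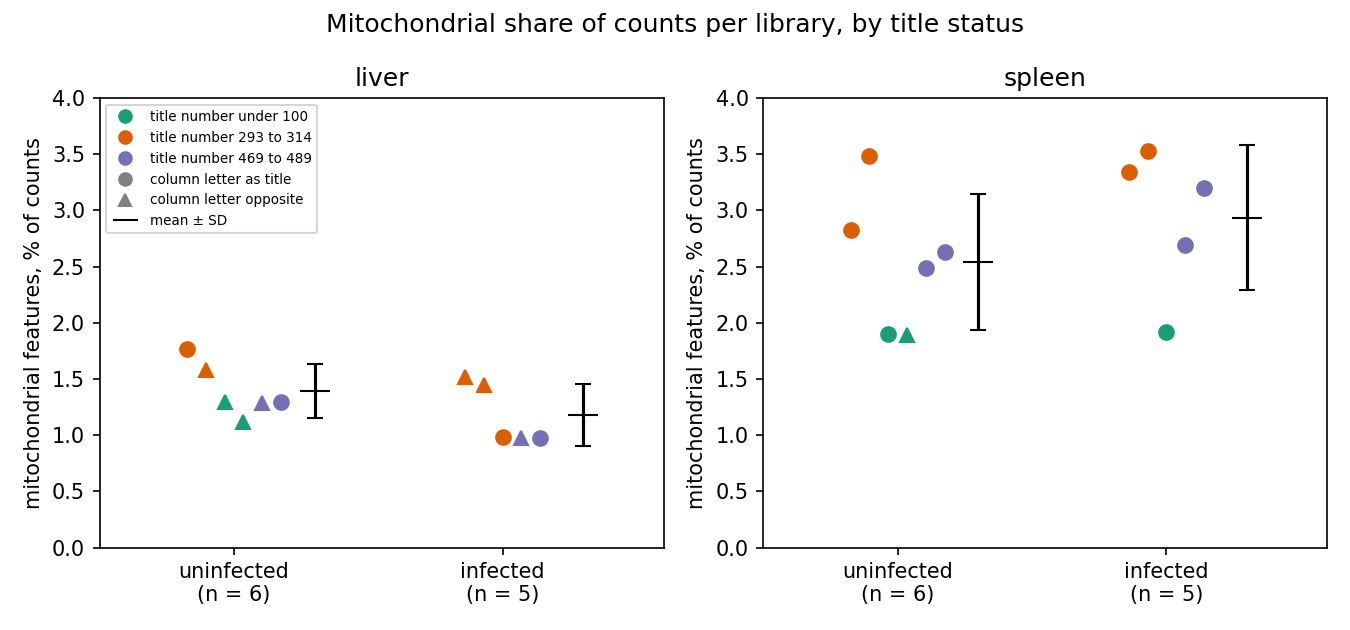
Share of counts on the 16 mitochondrial features (y axis, percent) in each liver and spleen library, by title status, with the mean ± SD beside each group. Colours give the run of title numbers and triangles mark libraries whose column letter opposes the title; in spleen the 3 libraries numbered under 100 sit between 1.89 and 1.92%, below all others.

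The same comparison in spleen asked which transcripts differed away from the site of the larvae. Mitochondrial features took 2.94% ± 0.65 (SD, n = 5) of the counts in infected and 2.54% ± 0.60 (SD, n = 6) in uninfected spleens, a difference of 0.397 percentage points (two-sided exact permutation test, p = 0.323). The difference was 0.0938 under the letters. Within the run numbered 293 to 308 it was 0.274, and within the run 473 to 488 it was 0.387. Each of those runs alone held 2 libraries per status, which cannot give an exact p below 0.333. With status permuted within all 3 runs at once, the exact permutation p was 0.065 by titles and 0.778 by letters. In liver the same permutation test gave 0.217 and 0.250. Of the complex I subunits, ND4L had the smallest p, with a log2 fold change of 0.51 ± 0.27 (SE) and means of 100.4 ± 26.7 CPM (SD, n = 5) and 78.0 ± 29.7 CPM (SD, n = 6). ND6, ND4, ND2, ND1 and ND5 had log2 fold changes of 0.37, 0.32, 0.24, 0.23 and 0.26, with SEs between 0.19 and 0.24. COX3 was at 0.27 ± 0.23 (SE), CYTB at 0.17 ± 0.21 (SE) and ATP8, a subunit of ATP synthase, at 0.93 ± 0.95 (SE). The estimate for trnP(ugg) was -0.53 ± 0.46 (SE).

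None of these 10 features passed the test. Under the letters ND4L, ND6, ND4, ND2, ND1 and ND5 were at 0.30, 0.14, 0.12, 0.09, 0.11 and -0.01. COX3 was at 0.13, CYTB at -0.01, ATP8 at 1.18 and trnP(ugg) at -0.53 there. With number run as a term ATP8 was at 0.38 ± 0.33 (SE), ND4L at 0.32 ± 0.14 (SE), ND6 at 0.21 ± 0.09 (SE) and trnP(ugg) at -0.47 ± 0.18 (SE). No feature passed in either fit. Leaving out 1 library moved 7 of the 10 estimates over 1.5-fold. Of all 16 named features 15 had estimates above 0 in infected spleen, with a median log2 fold change of 0.21. Under the letters 7 were above and 9 below 0, with a median of -0.01. The 13 messenger RNAs lay above other genes as a set by camera with a preset correlation (p = 5.11e-06). The correlation estimated from the libraries was 0.69, far above the preset one, so that p is too small. With the estimated correlation the messenger RNAs did not pass (camera, p = 0.152). Against no change, with the correlation among genes allowed for by fry, p was 0.256. Under the letters the preset correlation gave p = 0.240, the estimated correlation 0.699 and fry 0.797.

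One spleen gene, PFLUV_G00218700, named after its values were seen, was the only call of 2 fits described next. It averaged 28.9 ± 17.9 CPM (SD, n = 5) in infected and 7.41 ± 4.22 CPM (SD, n = 6) in uninfected spleens. In infected replicate 4 it was at 8.83 CPM, within the uninfected range of 4.14 to 15.4 CPM. Its log2 fold change was 2.16 ± 0.42 (SE), which did not pass in edgeR (adjusted p = 1.0). With number run as a term it was 2.24 ± 0.18 (SE) and passed (edgeR adjusted p = 0.005), and it passed in DESeq2 without that term (adjusted p = 0.009). Without infected replicate 3 the adjusted p of the edgeR fit with number run was 0.073, and it stayed below 0.05 in the other 10 fits that each left out 1 library. Under the letters the log2 fold change was 2.17 ± 0.55 (SE) and did not pass in edgeR or DESeq2. Across all 16657 spleen genes tested, edgeR called 0 at an adjusted p of 0.05, with 261 (1.57%) at an unadjusted p below 0.05. That is fewer than chance alone would give. This fit leaves the differences among number runs, described below, in its residual spread, and with number run as a term the share was 4.97%. Without that term the p-values ran high, so the 0 does not show that infection changed nothing. Under the letters edgeR gave 0 as well, DESeq2 gave 1 under the titles and 11 under the letters, and limma-voom gave 0 under the titles. With number run as a term edgeR gave 1 under the titles and 0 under the letters, and DESeq2 gave 30 and 141. Within the runs from 293 and from 473 edgeR called 0 in each.

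A joint fit of all 22 libraries asked whether the infection difference itself differed between the tissues. Among named features ND6, COX3, COX1, ND4L and CYTB had the smallest p. Their spleen differences exceeded their liver differences by 0.70, 0.66, 0.54, 0.50 and 0.42 on the log2 scale, with SEs of 0.39, 0.37, 0.39, 0.37 and 0.33. None passed (edgeR adjusted p = 1.0 for each). Under the letters the 5 values were 0.46, 0.50, 0.32, 0.84 and 0.25, and none passed. The spleen difference in mitochondrial share exceeded the liver difference by 0.610 percentage points (two-sided exact permutation test with status permuted within tissue, p = 0.142). Under the letters it was 0.287 (same permutation test, p = 0.497). The labels do not say which liver and spleen came from 1 fish, so the fit and this test treat all 22 libraries as independent. Of 14266 genes tested in both tissues, 0 passed in edgeR. An unadjusted p below 0.05 was found for 494 (3.46%), fewer than chance alone would give. DESeq2 gave 2 genes, both with a lower infection difference in spleen, and limma-voom gave 0. Under the letters edgeR and DESeq2 each gave 0. With number run as a term edgeR gave 0 under the titles. DESeq2 then gave 78, of which 38 had a higher and 40 a lower infection difference in spleen.

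Sex was compared in each tissue as a check on the labels and a scale for the infection difference. No liver gene of 15040 passed for females against males in edgeR, with 765 at an unadjusted p below 0.05. No spleen gene of 16657 passed, with 242 (1.45%) below that level, again fewer than chance alone would give. DESeq2, with its own filter, adjusted over 9626 genes in liver and 17158 in spleen. It gave 12 genes in liver, 7 higher in females and 5 lower, and 3 in spleen, 2 higher and 1 lower. With number run as a term DESeq2 adjusted over only 2558 genes in liver and over 17246 in spleen. It then gave 23 in liver, 22 higher and 1 lower, and 12 in spleen, 8 higher and 4 lower. By limma-voom the count was 0 in both tissues. Vitellogenin and egg envelope genes, which mature females express in liver, were on a list fixed beforehand, but could not be looked up because the identifiers carry no names.

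Spleen libraries grouped by number run more than by infection. Spearman correlations of counts, across genes within each pair of libraries, had a median of 0.973 for pairs of 1 run and 0.933 for pairs of different runs. Medians were 0.935 for pairs of equal title status and 0.943 for pairs of unequal status. With sex and infection in the model, 5516 of 16657 spleen genes (33.1%) differed among the 3 runs at an adjusted p of 0.05 in edgeR. In liver, with runs read from the doubtful headings, 0 of 15040 genes did, with 1771 at an unadjusted p below 0.05. That count therefore does not set liver apart from spleen. Genes are not independent replicates, and no p is attached to the correlations.

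Mitochondrial content also moved with run in spleen. The share of counts was 1.91% ± 0.01 (SD, n = 3) in the run under 100, 3.30% ± 0.32 (SD, n = 4) in the run from 293 and 2.75% ± 0.31 (SD, n = 4) in the run from 469 (exact permutation test of 11550 assignments, p = 0.001, and 0.008 adjusted over 8 tests). ATP8 averaged 9.09 ± 6.15 CPM (SD, n = 3), 3.48 ± 0.78 CPM (SD, n = 4) and 34.6 ± 9.5 CPM (SD, n = 4) in those runs (exact permutation test on log2(CPM + 1), p = 0.002, and 0.008 adjusted). PFLUV_G00150180, picked after its values were seen, had 22386 to 232662 counts in the 7 spleen libraries of the first 2 runs and 268 to 820 in the 4 of the last.

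**Figure D2:**
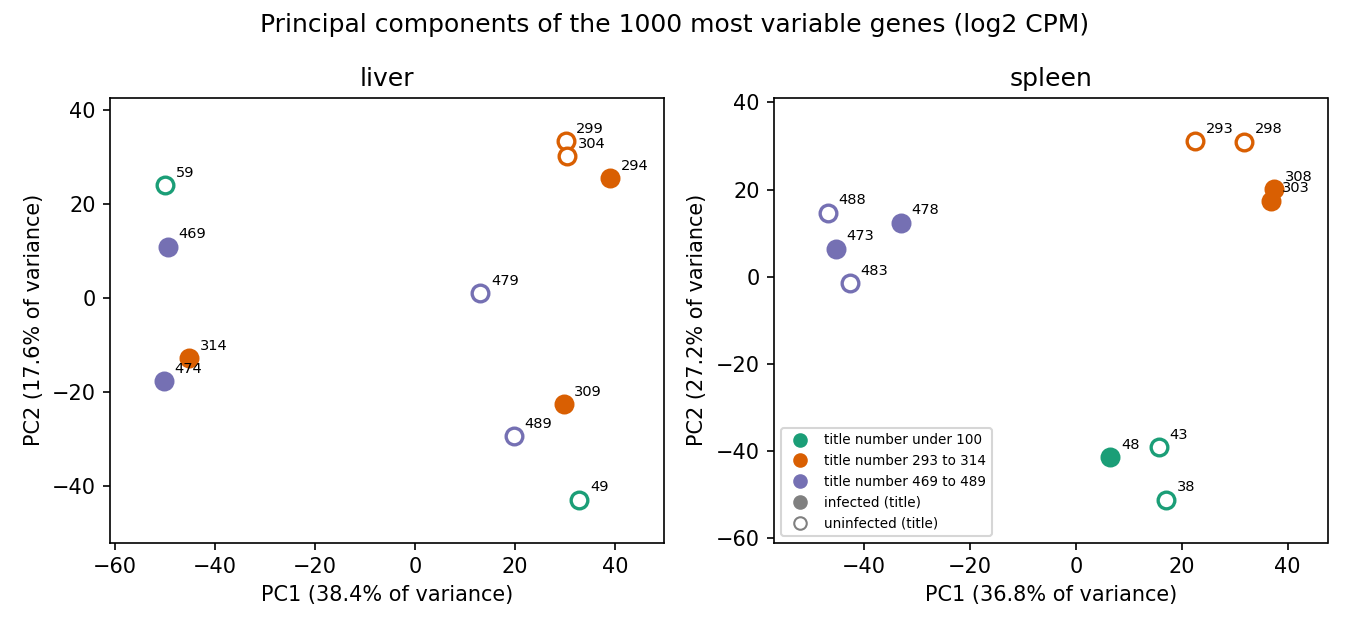
Principal components of log2 CPM over the 1000 most variable genes, liver on the left and spleen on the right, each point 1 library marked with its title number. Colours give the run of title numbers and filled points the libraries titled infected; spleen libraries form 3 clusters that follow the runs (36.8 and 27.2% of variance on the axes), while liver libraries of 1 run, read from headings that are in doubt, lie in different clusters (38.4 and 17.6%).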

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

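The values in this part were compared with the other libraries of their group after the data were seen. The values were total counts, share of mitochondrial counts, share of the 10 most counted genes and the 16 mitochondrial features. Of 76 comparisons of a group, 5 had 1 library far from the rest. Chance gives about 1 in 20, so 5 is close to the number that chance alone would give. Uninfected liver replicate 3 had 12.9% of its counts on its 10 most counted genes, against 21.9 to 24.3% in the other 5 libraries of its group. Infected spleen replicate 4 had 15.7%, against 8.18 to 9.29% in its group. ATP6, a subunit of ATP synthase, was at 2240 CPM in infected liver replicate 1, against 1460 to 1570 in the other 4. ND3, a subunit of complex I, was at 136 CPM in the same library, against 62.5 to 73.5. COX2 was at 3050 CPM in infected spleen replicate 3, the only infected spleen of the run numbered under 100, against 4980 to 5340 in the other 4. No feature or gene showed an infection difference that differed between liver and spleen past the edgeR threshold.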

How the results depend on the processing

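Fits by letters, within runs, on the libraries whose title and letter agree, or combining DESeq2 with other choices were chosen after the data were seen. So were all values for mitochondrial shares and for the test among runs. The other fits of the 5 comparisons were set beforehand. For all 5 comparisons edgeR gave 0 genes under RLE, no filter, the stricter filter, without the covariate and by limma-voom, and 0 in every fit without 1 library. The smallest adjusted p there was 0.070, in the interaction. For infection in liver DESeq2 gave 2 genes, by letters 21, by letters with number run 12, and by titles with number run 96. The 4 libraries whose title and letter agree gave 65, and the 4 of the run from 469 gave 437. Both set 2 libraries against 2 that also lie apart on the first principal component of liver. For infection in spleen DESeq2 gave 1, edgeR with number run 1, and DESeq2 by letters 11, by letters with number run 141, and with number run 30. For sex the same DESeq2 fits (titles, letters, letters with run, titles with run) gave 12, 19, 36 and 23 genes in liver and 3, 4, 42 and 12 in spleen. For the interaction DESeq2 gave 2, by letters with run 12 of only 990 genes that it adjusted over, and with run 78. The cause was not tested.

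Of the named features s-rRNA in liver turned to -0.29 within the run from 294. ND5 and CYTB in spleen turned to -0.01 each by letters, and CYTB to -0.02 within the run from 293; the cause was not tested. The liver share of mitochondrial counts kept its sign (-0.298 to -0.138 points without 1 library), as did the spleen share (0.249 to 0.651). The count of 5516 spleen genes among runs ranged from 3927 to 6341 without 1 library. No paired analysis of infected against uninfected libraries was possible, because the labels link none of them. Liver and spleen libraries of neighbouring numbers were not fitted as pairs, since no label calls them 1 fish. The gene list alternatives were not run, since no entry matched. In simulated liver data 11% of genes changed 2-fold were recovered, so a count of 0 leaves such changes open.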

Other observations

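The tests in this part were all chosen after the data were seen, apart from the 5 comparisons whose splits are counted at the end. Liver and spleen differed in which mitochondrial messages they held, a comparison that rests on the ratio of features within a library and on no scaling. ATP6 made up 13.2% ± 2.2 (SD, n = 11) of the mitochondrial counts in liver and 7.56% ± 0.76 (SD, n = 11) in spleen. ND2, a subunit of complex I, made up 7.64% ± 1.07 and 4.28% ± 0.40. COX1 was the reverse, with 22.4% ± 2.1 in liver and 27.9% ± 1.6 in spleen, as was CYTB, with 11.85% ± 0.82 and 13.95% ± 0.61. For these 4 features no liver library overlapped a spleen library (permutation test, adjusted p = 9e-05 each over 18 tests). ND5 (2.75 against 2.18%, adjusted p = 0.043) and ND6 (0.630 against 0.472%, adjusted p = 0.007) were also higher in liver, and COX3 higher in spleen (15.2 against 17.3%, adjusted p = 0.023). The other 9 features did not pass. Some libraries of the 2 tissues may share a fish, which these permutations do not model.

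The total amount of mitochondrial RNA has no scale-free order between tissues. Over genes in both tables it was 1.65% ± 0.34 (SD, n = 11) of liver counts and 2.76% ± 0.63 (SD, n = 11) of spleen counts. On TMM-scaled totals the order turned, with 2.56% ± 0.61 in liver and 1.80% ± 0.43 in spleen.

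The first pattern is that liver libraries matched spleen libraries of another number run. Over 63 genes that were on in some libraries and off in others in both tissues, 6 of 11 livers agreed best with a spleen of their own run, a count that shuffled names often reach (permutation p = 0.188). The liver titled 479 agreed best with spleen 48, at 93.7% of genes, and livers 59 and 314 agreed best with spleens 478 and 473. The spleen columns stand in text order of their names and the liver columns do not. A candidate explanation is that the liver headings are out of order: with the liver names in text order, 11 of 11 livers matched a spleen of their own run (permutation p = 3e-04), and 6 rather than 2 of 8 livers matched the spleen numbered 1 lower. Over 4 other settings the own-run count was 9 to 11 in text order and 4 to 6 under the headings. The count of matches 1 lower depended on the setting, with 4 against 3 at a gap of 1.5 and 6 against 2 at 2.5. It was 5 against 2 by correlation over all shared genes. Over 87 genes it was 2 against 1, when genes that vary together in both tissues, left out of the 63, were kept. RNA of another tissue, for which those co-varying genes were taken as a sign, stays open as a partial source. Leaving them out raised the own-run count under the headings from 4 to 6 of 11, and the bounds of this test were set with both counts known.

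If neighbouring numbers mark the liver and spleen of 1 perch, the 22 libraries come from 14 fish. Counting a fish as infected when either tissue is marked so gives 8 infected and 6 uninfected fish, the numbers in the series description. Titles and letters both give that count, so it favours neither. The letters agree in 7 of the 8 pairs of neighbouring numbers, the titles in 4 and the sex labels in 4. Whether titles or letters are right stays open. The order of headings that gave 11 of 11 matches was found in the same data. In that order the first principal component of the livers parts the 3 runs, at 13.05 to 19.71, 29.66 to 38.97 and -50.16 to -45.16. The libraries headed 469 and 474 would be named 479 and 489 and stay in the last run. Those headed 479 and 489 would be named 49 and 59 and move to the first. Each of those new names is titled uninfected. By titles the 437 genes would then separate uninfected livers of different runs, with no infected library among them. No comparison of infected with uninfected livers was made under the other order.

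The second pattern is the number-run difference of spleen. The real runs gave 5516 genes, and 1 of 100 splits of the same libraries, the real one, gave as many. The highest of the others gave 3471. Chance is therefore an unlikely source, but 100 splits are too few to exclude it. The tables argue against depth, as thinning all libraries to 12132833 counts left 5468 genes. They argue against a few abundant genes too, as 5502 were called without the 10 most counted genes of each library. Lake of origin, sampling date and library batch stay open as untested, since no label gives them.

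The third pattern is ATP8, which differed 9.93-fold between the highest and lowest run means of spleen. ATP6 lies on the same transcript and differed 1.49-fold, which argues against the amount of mitochondrial RNA. A sequence variant against the reference, which could keep reads of some fish from aligning over this short gene, cannot be told apart from other sources. Liver run means of 29.8 ± 6.2 (SD, n = 2), 8.62 ± 12.77 (SD, n = 5) and 23.0 ± 7.5 CPM (SD, n = 4) decide nothing while the headings are in doubt. The second mean spans 2.38 to 31.4 CPM, with the highest value in liver 314. With the names in text order the runs would span 16.4 to 16.6, 2.38 to 25.4 and 28.6 to 34.1 CPM. In the second run the liver headed 49 would be at 25.4 CPM and the others at 2.38 to 3.81. The spleens of that run were at 2.81 to 4.61 CPM. Libraries of 1 run would thus not all be alike, and these spans do not decide on a variant.

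Splits of the libraries say nothing for the 5 comparisons with a count of 0, since 100 of 100 splits gave at least as many genes, and chance cannot be excluded. The highest other split gave 368 genes for infection in liver, 2251 in spleen, 88 for sex in liver, 1473 in spleen and 405 for the interaction. Such counts point to a structure of the samples: the highest spleen splits for infection and for sex set the 4 libraries numbered 293 to 308 and 1 other against the rest. Within that run edgeR gave 0 genes for infection in spleen.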
